A study of Mus musculus with 6 samples.

How the data were processed

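RNA from KVTR cells, mouse cells that the labels describe as primary clear cell renal carcinoma cells, was sequenced after dopamine treatment or without it (blank). Per the labels' protocols, a SMART-Seq HT kit was used, which amplifies full-length cDNA from small inputs. Libraries were then built with a Vazyme DNA library kit and read as 150 bp pairs on an Illumina NovaSeq sequencer. That chemistry does not mark strand, so reads from overlapping or antisense genes cannot be assigned by strand, and near-identical paralogs and pseudogenes can share reads. Each group had 3 libraries.

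The authors deposited a table of 56691 Ensembl genes with a raw read count and an FPKM value per gene and library, per the file headers. Genome build GRCm39 is named in the submitters' processing notes. The aligner, the counting program, its strand setting and the gene annotation release are not given in the sources used here. The deposited FPKM values equal the count divided by the exonic gene length in kilobases and by a library total, on a fixed scale, within a rounding tolerance of 0.005, for the 4 libraries with an FPKM column matched to a sample. That total was the sum of the counts, except in dopamine 1, where it was 2995 to 3000 counts lower and the value of Tap1 matched neither total. In addition, 2 per-library FPKM columns, which no label ties to a single sample, were not used here. FPKM values used in filters and alternatives were recomputed from the counts.

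Count columns were matched to samples by the sample names in the labels. Of the blank columns, 2 carry the numbers 2 and 3 and the other carries no number. The last was used as a blank library without a number and is called the unnumbered blank library. The labels do not say whether libraries came from separate cultures. Total counts were 17954949, 18179787 and 19766071 in blank 2, blank 3 and the unnumbered blank library, and 16771499, 23375622 and 23354455 in dopamine 1, 2 and 3. A gene with no count in a library could be present at up to 3 counts, which is 0.128 to 0.179 CPM of these unscaled totals. Such bounds cover counting error only, because amplified reads without molecular identifiers are not independent molecules.

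Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr (15420) were scaled with TMM factors and tested with the quasi-likelihood test, dopamine against blank, 2-sided, with no covariate. The threshold was a Benjamini-Hochberg adjusted p of 0.05 with no minimum fold. Standard errors of log2 fold changes are the size of the log2 fold change divided by the square root of the F statistic. CPM values are counts divided by the TMM-scaled library size, as edgeR gives them, and means are given ± SD over 3 libraries. Before the data were examined, 28 gene lists were fixed, holding 995 symbols. Of these symbols, 22 were joined to the table through RefSeq synonyms and 6 had no match. Lists with at least 5 tested members (27) were tested with limma 3.58.1's camera at a preset inter-gene correlation of 0.01, and again with the correlation estimated per list and with fry, each with Benjamini-Hochberg adjustment over the 27 lists. Library composition was compared with an exact permutation test, 2-sided, for which 3 against 3 cannot give a p under 0.1.

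The genes named were also set by a rule fixed before the data were examined. Because no gene passed the threshold, the rule took the 5 genes of smallest p in each direction among genes with a mean FPKM of at least 5 in the higher group, no overlap between the 3 dopamine and 3 blank values, and a symbol that is not a predicted gene name. It also took a fixed panel of dopamine, immune, oxidative, hypoxia, splicing and immediate early genes. Part of that panel is not reported here. Members of lists named outside this rule were chosen after their values were seen: Mki67, Rrm2, Col6a3, Pdgfra, Fn1, Osgin1, Txnrd1, Cd68, Lyz2 and Tap1, and the cell type genes whose levels are given without a test. Gene positions are those of the deposited table (GRCm39). The reference annotation at hand was on another build and its coordinates were not used here.

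The edgeR, DESeq2 and limma steps were tested on simulated data drawn from the means, dispersions and library sizes of the real libraries for this comparison (15420 genes, 200 of them changed). edgeR called 2 of 50 genes changed 2-fold, 18 of 50 changed 4-fold, 38 of 50 changed 8-fold and 42 of 50 changed 16-fold, with 9 unchanged genes called. In a single draw with no gene changed, edgeR called 0 genes, limma 0 and DESeq2 52. With 2 lists shifted 1.5-fold, camera called both at the preset and at the estimated correlation, and 0 other lists. The simulated genes were drawn independently of each other. In the real libraries the estimated inter-gene correlation was 0.912 for the G2 and M phase list and 0.791 for the S phase list. The simulation therefore cannot show how often camera calls unchanged lists of correlated genes. Nor can it show how often camera with an estimated correlation misses shifted lists of such genes.

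Alternatives fixed before the data were examined were DESeq2 1.42.0, median-of-ratios factors in edgeR, no filter beyond a count above 0 in at least 1 library, and an FPKM of at least 5 in at least 3 libraries. Others were limma on log2(FPKM + 1) of genes at an FPKM of at least 1 in at least 3 libraries, with and without a variance trend, on log2(FPKM + 0.1), on log2(TPM + 1), with median-of-ratios factors and after quantile normalization. Further ones were an added minimum absolute log2 fold change of 1, a replicate block, and each library left out in turn. Alternatives added after the data were seen were the 4 libraries numbered 2 and 3 without a block, the Tap1 count of dopamine 1 set to what its library total leaves, and the tests without mitochondrial genes and the 18S ribosomal RNA gene. To compare libraries at equal total counts, counts were thinned at random to about 16771499 per library, in 10 draws. Ranges over alternatives leave out the replicate block. Alternative splicing needs reads or junction counts and was not analysed here.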

Results

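Transcript levels were measured by RNA-seq in KVTR cells, which the labels describe as mouse primary clear cell renal carcinoma cells, with and without dopamine. Clear cell renal carcinoma is a kidney cancer of tubule epithelium. Dopamine is a catecholamine transmitter that the transporter Slc6a3 carries into cells, and the series title joins Slc6a3 to the spliceosome and to resistance against checkpoint inhibitors. The comparison asks which transcripts differ in abundance after dopamine. Dose and duration are not given in the sources used here. Gene counts were available for 3 dopamine and 3 blank libraries, with totals of 16771499 to 23375622 counts. Because the labels do not say that libraries came from separate cultures, p-values measure the spread between these libraries, which may be technical.

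Libraries did not sort by treatment. Dopamine 2 and dopamine 3 correlated at r = 0.983 across the 15420 genes tested (log2 CPM), and blank 2 correlated with them at 0.979 and 0.978, above its 0.950 with blank 3 and 0.912 with the unnumbered blank library. Dopamine 1 correlated at 0.910 and 0.904 with dopamine 2 and 3. These are correlations across genes, which are not independent replicates. Over pairs of libraries, r ranged from 0.904 to 0.983 within groups (median 0.911, 6 pairs) and from 0.898 to 0.979 between groups (median 0.939, 9 pairs). The first principal component held 48.2% of the variance, of which 3.27% lay between the groups, and the third held 13.2%, of which 69.2% lay between the groups (exact permutation test, 2-sided, p = 0.1, the smallest that 3 against 3 allow).

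**Figure D1:**
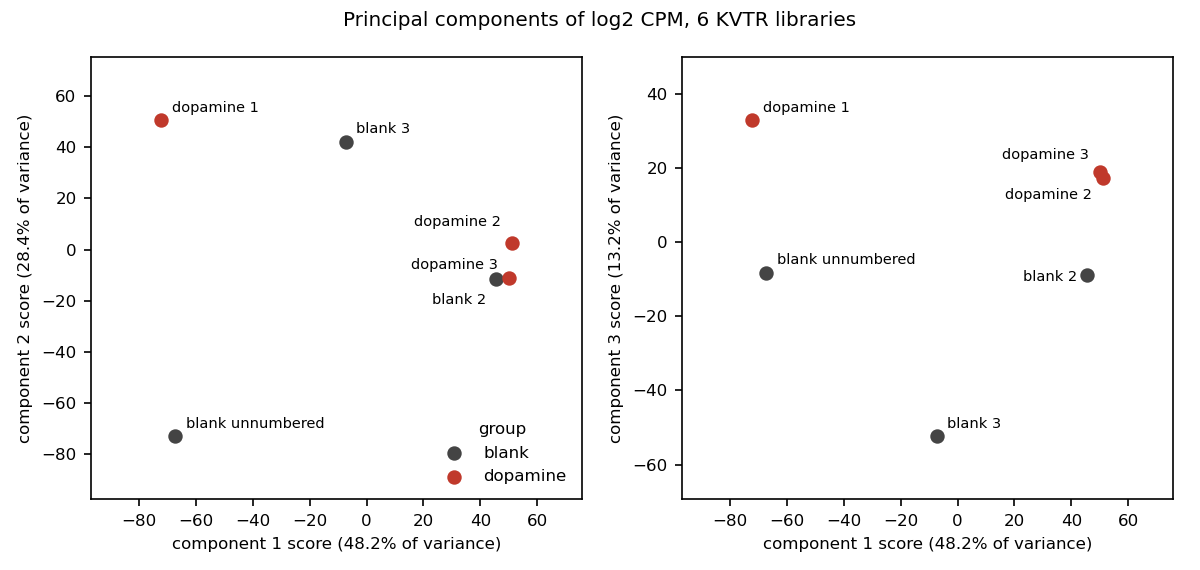
Scores of the 6 libraries on principal components 1 and 2 (left) and 1 and 3 (right) of log2 CPM, with the percentage of variance on each axis and 1 point per library coloured by group. Blank 2 (score 45.6) lies beside dopamine 2 (51.0) and dopamine 3 (49.9) on component 1, and dopamine 1 (-72.1) beside the unnumbered blank library (-67.1). On component 2, dopamine 1 (50.7) and the unnumbered blank library (-73.0) lie at opposite ends.

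Mitochondrially encoded transcripts took 4.44% ± 0.32 of counts in blank and 3.60% ± 0.47 in dopamine libraries (SD, n = 3; exact permutation test, p = 0.1, adjusted p = 0.6 over 6 measures). Cytosolic ribosomal protein genes took 1.94% ± 0.63 and 1.78% ± 0.36 of counts (exact permutation p = 0.7), the 18S ribosomal RNA gene 1.81% ± 0.73 and 2.23% ± 1.0 (exact permutation p = 0.7), and the 20 most abundant genes 11.4% ± 0.89 and 11.6% ± 2.22 (exact permutation p = 0.9). Genes at an FPKM of at least 1 numbered 12458 ± 137 in blank and 12265 ± 113 in dopamine libraries (exact permutation p = 0.2), and total counts gave an exact permutation p of 0.4.

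Dopamine-treated libraries held more transcript of Slc1a5, a neutral amino acid transporter that takes up glutamine, at 45.3 ± 7.60 CPM against 19.3 ± 2.73 in blank libraries (log2 fold change 1.23 ± 0.22 SE, n = 3 per group). Por, the electron donor of microsomal cytochrome P450 enzymes, stood at 419 ± 146 CPM against 167 ± 7.25 (1.33 ± 0.28). Ifitm10 (1.08 ± 0.21), S100a13 (1.12 ± 0.25) and S100a16 (1.13 ± 0.27), the last a pair of S100 calcium-binding protein genes, were also higher in each dopamine library than in any blank library. Lower in each dopamine library were Dock5, a guanine nucleotide exchange factor for Rac (25.8 ± 1.44 against 73.0 ± 24.2 CPM, -1.50 ± 0.28), Aldh1a2, a retinoic acid synthesising enzyme (7.17 ± 0.78 against 24.9 ± 13 CPM, -1.80 ± 0.39), Zfp36, an mRNA decay factor (17.6 ± 1.05 against 31.3 ± 1.70 CPM, -0.83 ± 0.18), the microfibril gene Fbn1 (-1.35 ± 0.32) and the alarmin cytokine Il33 (-1.07 ± 0.26).

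None of these 10 genes passed the threshold. edgeR's quasi-likelihood test called 0 of 15420 genes after Benjamini-Hochberg adjustment (smallest adjusted p = 0.9997). An unadjusted p under 0.05 was found for 454 genes, 161 of them higher and 293 lower with dopamine. This is fewer than 771, which is 5% of the genes tested. All 3 dopamine values lay outside the 3 blank values for 1307 genes (617 above, 690 below), which is 8.48% of those tested, where 10% is the share chance gives. DESeq2 called 20 genes, 6 higher and 14 lower, among them Slc1a5 (adjusted p = 0.0140), Ifitm10 (0.0323), Por (0.0375), Dock5 (0.0185), Zfp36 (0.0262) and Aldh1a2 (0.0324). Over the alternatives, the adjusted p of these 6 genes ran from 0.0140 to 1. In a single draw of simulated libraries of the same spread with no gene changed, DESeq2 called 52. In the real libraries it called 20 or more genes in 3 of the 10 splits into 3 against 3, dopamine against blank included. limma on log2(FPKM + 1) called 0 of 12506 genes, with 306 at an unadjusted p under 0.05. The biological coefficient of variation was 0.427.

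**Figure D2:**
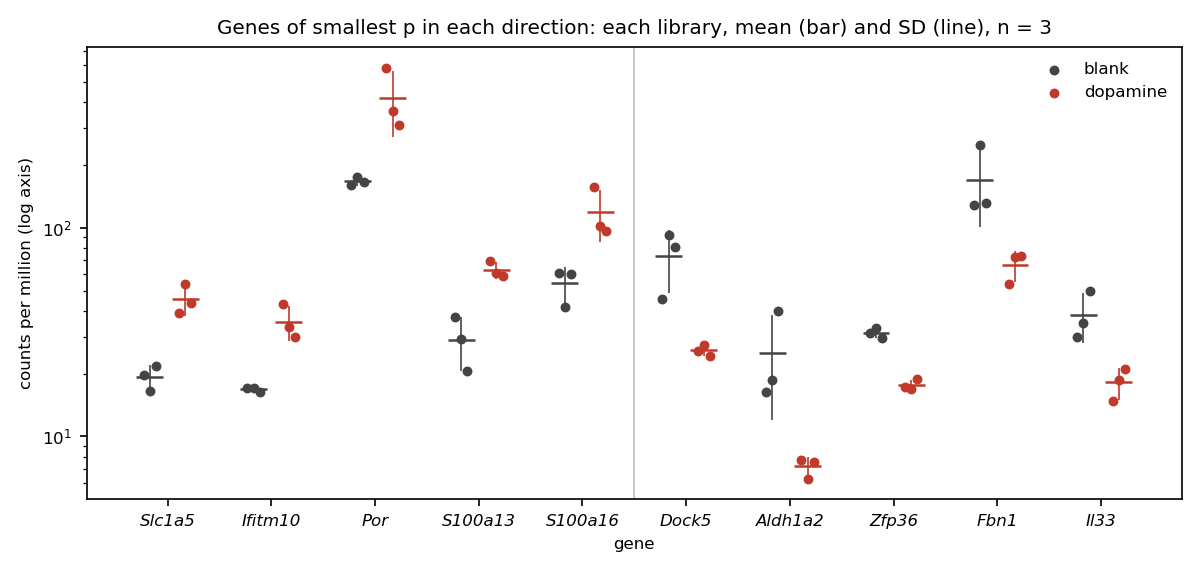
CPM (log axis) in each of the 3 blank and 3 dopamine libraries for the 5 genes of smallest p in each direction, with the mean as a bar and the SD as a line. The genes were chosen for not overlapping between groups, and none passed the adjusted threshold in edgeR (adjusted p = 0.9997).

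In the deposited table (GRCm39), Slc1a5 (ENSMUSG00000001918) spans 16515265 to 16532199 of chromosome 7, where Ifitm10 (ENSMUSG00000045777, 141879574 to 141927490) and Zfp36 (ENSMUSG00000044786, 28076209 to 28079678) also lie. Por (ENSMUSG00000005514) is at 135698887 to 135764180 of chromosome 5. S100a13 (ENSMUSG00000042312, 90421742 to 90431888) and S100a16 (ENSMUSG00000074457, 90444561 to 90450458) are on chromosome 3. Dock5 (ENSMUSG00000044447) is at 67989584 to 68170891 of chromosome 14, Aldh1a2 (ENSMUSG00000013584) at 71123071 to 71203525 of chromosome 9, Fbn1 (ENSMUSG00000027204) at 125142514 to 125349913 of chromosome 2 and Il33 (ENSMUSG00000024810) at 29902514 to 29938118 of chromosome 19. These are whole gene spans.

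Transcripts of the dopamine transporter Slc6a3 and of the receptors Drd1, Drd3 and Drd5 were too low to test, and those of Drd2 and Drd4 stayed at 1.55 CPM or less in each library. Slc6a3 had 1, 12 and 1 counts in blank 2, blank 3 and the unnumbered blank library and 1, 2 and 3 in dopamine 1, 2 and 3. Drd1 had 9 counts over the 6 libraries, Drd3 had 2 and Drd5 had 0, which allows up to 0.179 CPM in the shallowest library. Drd2 averaged 0.55 ± 0.62 CPM in blank and 0.69 ± 0.39 CPM in dopamine libraries (log2 fold change 0.30 ± 1.11), and Drd4 0.86 ± 0.24 and 1.05 ± 0.43 CPM (0.29 ± 0.50). The sign for Drd2 turned without blank 2 (-0.28) or dopamine 1 (-0.10), and that for Drd4 without dopamine 2 (-0.11). Only these 2 of the 5 receptor genes were tested, too few for a list test. Maoa, a monoamine oxidase that degrades dopamine, stood at 270.5 ± 125 CPM in blank and 403 ± 224 CPM in dopamine libraries (0.57 ± 0.56, edgeR adjusted p = 0.9997). Of 19 genes of dopamine transport and metabolism, 7 were tested and all 7 lay on the higher side, with a median of 0.38 (camera adjusted p = 0.0200; adjusted p = 0.442 with an estimated correlation). By edgeR 0 of them passed over all genes or adjusted over the list alone, 0 had an unadjusted p under 0.05, and DESeq2 called 0. Over the other alternatives the camera adjusted p ran from 0.00386 to 0.247, and the call ended with no filter on low counts (median 0.37), in limma after quantile normalization (0.36), without the unnumbered blank library (0.27) and without dopamine 2 (0.34).

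Genes of the splicing machinery gave no call with all 6 libraries in edgeR. The core spliceosome list (81 tested genes) had a median log2 fold change of 0.06 (camera adjusted p = 0.443), with 49 members on the higher side, and the list of SR proteins, hnRNP proteins and other splicing regulators (77 tested) a median of -0.05 (camera adjusted p = 0.367), with 32 on the higher side. In edgeR, 0 members of either list passed over all genes or adjusted over the list alone, with 0 and 1 at an unadjusted p under 0.05, and DESeq2 called 0. Srsf1, an SR protein of exon definition, was at 178.5 ± 41.9 CPM in blank and 157 ± 59.6 CPM in dopamine libraries (-0.18 ± 0.34, 95% interval -1.0 to 0.63). Its sign turned to 0.02 without the unnumbered blank library and to 0.09 without dopamine 2. Sf3b1, a U2 snRNP subunit, was at 248 ± 11.8 and 229 ± 35.7 CPM (-0.12 ± 0.20, 95% interval -0.59 to 0.36). Nonsense-mediated decay factors (18 tested) had a median of -0.03 and a mean of -0.0024, with camera direction up (adjusted p = 0.910). Without the unnumbered blank library the core spliceosome list passed camera with a median of 0.13 (adjusted p = 0.678 with an estimated correlation), and without dopamine 1 the regulators passed with a median of -0.15 (adjusted p = 0.660 with an estimated correlation). Both signs also turned, without passing camera. The regulator median was 0.08 without the unnumbered blank library, and the core median reached -0.04 with a different library left out. The regulators also passed camera with all 6 libraries in limma after quantile normalization (median -0.095; adjusted p = 0.898 with an estimated correlation). Over the alternatives the camera adjusted p ran from 0.00142 to 0.931 for the core list and from 0.0203 to 0.715 for the regulators. With an estimated correlation and all 6 libraries the adjusted p was 0.975 for both.

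Cell cycle genes lay on the lower side in the dopamine group, largely through the level of a single blank library. The G2 and M phase list (39 tested) had a median log2 fold change of -2.38 (camera adjusted p = 8.98e-24) with 0 members on the higher side, and the S phase list (37 tested) a median of -1.0 (camera adjusted p = 3.79e-15), also with 0. With an estimated correlation the adjusted p was 0.591 for both. By edgeR 0 members of either passed over all genes or adjusted over the list alone, with 17 and 6 at an unadjusted p under 0.05, and DESeq2 called 3 and 0 (Ccnb2, Kif11 and Ube2c). Mki67, a marker of dividing cells, stood at 73.2 CPM in the unnumbered blank library and at 0.80 to 4.57 CPM in the other 5, and Rrm2, a ribonucleotide reductase subunit, at 147 CPM there and 6.46 to 13.1 CPM elsewhere. Without that library the medians were -0.33 for G2 and M phase and -0.18 for S phase. Over the alternatives the camera adjusted p ran from 7.68e-49 to 0.000167 and from 1.75e-22 to 0.0227. The same library held 381 CPM of the imprinted RNA H19, which stayed at 1.77 to 7.68 CPM in the others.

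Fibroblast and pericyte markers (18 tested) had a median of -0.58 (camera adjusted p = 3.66e-09; adjusted p = 0.323 with an estimated correlation), with 3 members on the higher side. By edgeR 0 members passed over all genes, 5 had an unadjusted p under 0.05, and 1 passed adjusted over the list alone, which DESeq2 also called. This was Col6a3, a collagen VI chain at 8.19 ± 5.87 CPM in blank and 1.09 ± 0.35 CPM in dopamine libraries (-2.91 ± 0.62, list-alone adjusted p = 0.0421 by edgeR; DESeq2 adjusted p = 0.0140 over all genes). Pdgfra, a growth factor receptor of mesenchymal cells, was at 20.9 to 24.5 CPM in blank and 10.4 to 14.1 CPM in dopamine libraries (-0.91 ± 0.23). Most of the shift came from dopamine 1, where the list mean lay at -1.52 log2 units relative to the 6 libraries, against 0.08 in dopamine 2, 0.18 in dopamine 3 and 0.28 to 0.51 in blank libraries, and without it the median was -0.10. Over the alternatives the camera adjusted p ran from 1.35e-11 to 0.0153. Mesenchymal genes (27 tested) had a median of -0.36 (camera adjusted p = 0.00341; adjusted p = 0.323 with an estimated correlation). They include Fn1, the matrix protein fibronectin, at 2158 to 3881 CPM in dopamine and 3820 to 11746 CPM in blank libraries (-1.15 ± 0.53). Blank 3 held the 11746 CPM and blank 2 4885 CPM, and the log2 fold change of Fn1 ran from -1.44 to -0.50 over the alternatives. The mesenchymal call ended without the unnumbered blank library (median -0.13) and with the 4 libraries numbered 2 and 3 alone (-0.14), and the camera adjusted p ran from 0.000633 to 0.124 over the alternatives. By edgeR 0 mesenchymal genes passed over all genes or adjusted over the list alone, 1 had an unadjusted p under 0.05, and DESeq2 called 0.

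Antioxidant genes driven by NRF2 were on the higher side in 36 of 40 tested members, with a median of 0.46 (camera adjusted p = 2.07e-06; adjusted p = 0.676 with an estimated correlation). By edgeR 0 members passed over all genes or adjusted over the list alone, 4 had an unadjusted p under 0.05, and DESeq2 called 0. The list mean lay at 0.37 in blank 2, 0.56 in dopamine 2 and 0.62 in dopamine 3, as log2 CPM relative to the 6 libraries, and at -0.07 in blank 3, -0.51 in dopamine 1 and -0.98 in the unnumbered blank library. Osgin1, an oxidative stress-induced growth inhibitor, was at 29.1 to 34.2 CPM in dopamine and 8.15 to 17.1 CPM in blank libraries (1.24 ± 0.31), and Txnrd1, cytosolic thioredoxin reductase, at 1376 to 2514 and 614 to 1235 CPM (0.96 ± 0.38). Of the panel, Nqo1, a quinone reductase, gave 0.51 ± 0.46, and Hmox1, heme oxygenase, gave 0.16 ± 1.06 with values from 146 CPM in the unnumbered blank library to 2414 CPM in blank 2. Hmox1 turned to the lower side without the unnumbered blank library (-0.37), without dopamine 2 (-0.18) or without dopamine 3 (-0.21). The NRF2 call ended without the unnumbered blank library (median 0.22), and its camera adjusted p ran from 1.89e-10 to 0.0882 over the alternatives.

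Nuclear genes of oxidative phosphorylation were on the higher side in 69 of 70 members (median 0.18, camera adjusted p = 1.66e-05; adjusted p = 0.690 with an estimated correlation), and the call ended without dopamine 3 (median 0.09). Their camera adjusted p ran from 6.14e-07 to 0.106 over the alternatives. Cytosolic heat shock genes were on the higher side in 20 of 22 (median 0.21, camera adjusted p = 0.00414; adjusted p = 0.402 with an estimated correlation), and the call ended without dopamine 1 (median 0.09), at an FPKM of at least 5 (0.17) and in limma after quantile normalization (0.15), with a camera adjusted p of 0.000148 to 0.0960 over the alternatives. By edgeR 0 members of either list passed over all genes or adjusted over the list alone, 0 had an unadjusted p under 0.05, and DESeq2 called 0.

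Interferon and antigen presentation genes varied between libraries within each group. The interferon response list (42 tested, median 0.27, camera adjusted p = 0.0595) lay at 0.86 in blank 2, 0.51 in dopamine 2 and 1.31 in dopamine 3, as mean log2 CPM relative to the 6 libraries, and at -1.48 in blank 3 and -1.42 in dopamine 1. Class I antigen presentation (23 tested, median 0.31, camera adjusted p = 0.0617) followed the same libraries, with B2m, the light chain of MHC class I, at 413 ± 126 CPM in blank and 429 ± 181 CPM in dopamine libraries (0.06 ± 0.41). The sign for B2m turned without blank 3 (-0.14), dopamine 2 (-0.18) or dopamine 3 (-0.10) and under limma on FPKM values (-0.06). Cd274, which encodes the checkpoint ligand PD-L1, was at 6.14 ± 2.72 and 10.9 ± 3.97 CPM (0.83 ± 0.44, edgeR adjusted p = 0.9997), and checkpoint and immune evasion genes (24 tested) had a median of -0.04 (camera adjusted p = 0.80). Leukocyte markers (8 tested of 26) had a median of 0.69 (camera adjusted p = 0.00706; adjusted p = 0.676 with an estimated correlation), with Cd68 at 62.9 to 128 CPM in dopamine and 19.7 to 55.0 CPM in blank libraries (1.27 ± 0.43). Of the 26 markers, 19 stayed below 1 CPM in all 6 libraries. Lyz2, a macrophage lysozyme gene, was at 34.0 CPM in blank 2, 38.3 in dopamine 2 and 32.9 in dopamine 3 but at 0.59 in blank 3 and 0.92 in dopamine 1. The leukocyte call ended without blank 3 (median 0.34), dopamine 2 (0.29) or dopamine 3 (0.46). With each library left out in turn the leukocyte median ran from 0.29 to 1.53, and over the alternatives its camera adjusted p ran from 3.54e-05 to 0.343. Interferon genes passed camera without blank 2 (median 0.60), the unnumbered blank library (0.33) or dopamine 1 (0.64), and class I presentation without blank 2 (0.56) or dopamine 1 (0.53). With each library left out in turn, the medians ran from -0.28 to 0.64 for interferon and from -0.07 to 0.56 for class I genes. The sign of both lists thus turned. With the 4 libraries numbered 2 and 3 alone their medians were 0.70 and 0.61, also past camera. With all 6 libraries both passed in DESeq2 (0.26 and 0.30, where no correlation was estimated), interferon genes with median-of-ratios factors (0.26) or without mitochondrial and 18S genes (0.26), and class I presentation with no filter (0.30). With an estimated correlation none of these edgeR calls held, at an adjusted p of 0.578 to 0.980 for interferon and 0.543 to 0.849 for class I genes. Over the alternatives their camera adjusted p ran from 1.37e-09 to 0.395 and from 9.19e-07 to 0.980. Of these 4 immune lists, edgeR passed 0 members over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 0 interferon, 1 class I, 3 checkpoint and 1 leukocyte genes, and DESeq2 called 0. The class I gene was Tap1 (1.14 ± 0.44), whose count in dopamine 1 is at odds with its deposited FPKM. With the count that the library total leaves for Tap1 (0.12), edgeR left 0 class I genes at an unadjusted p under 0.05. The count that its deposited FPKM corresponds to was not tested.

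**Figure D3:**
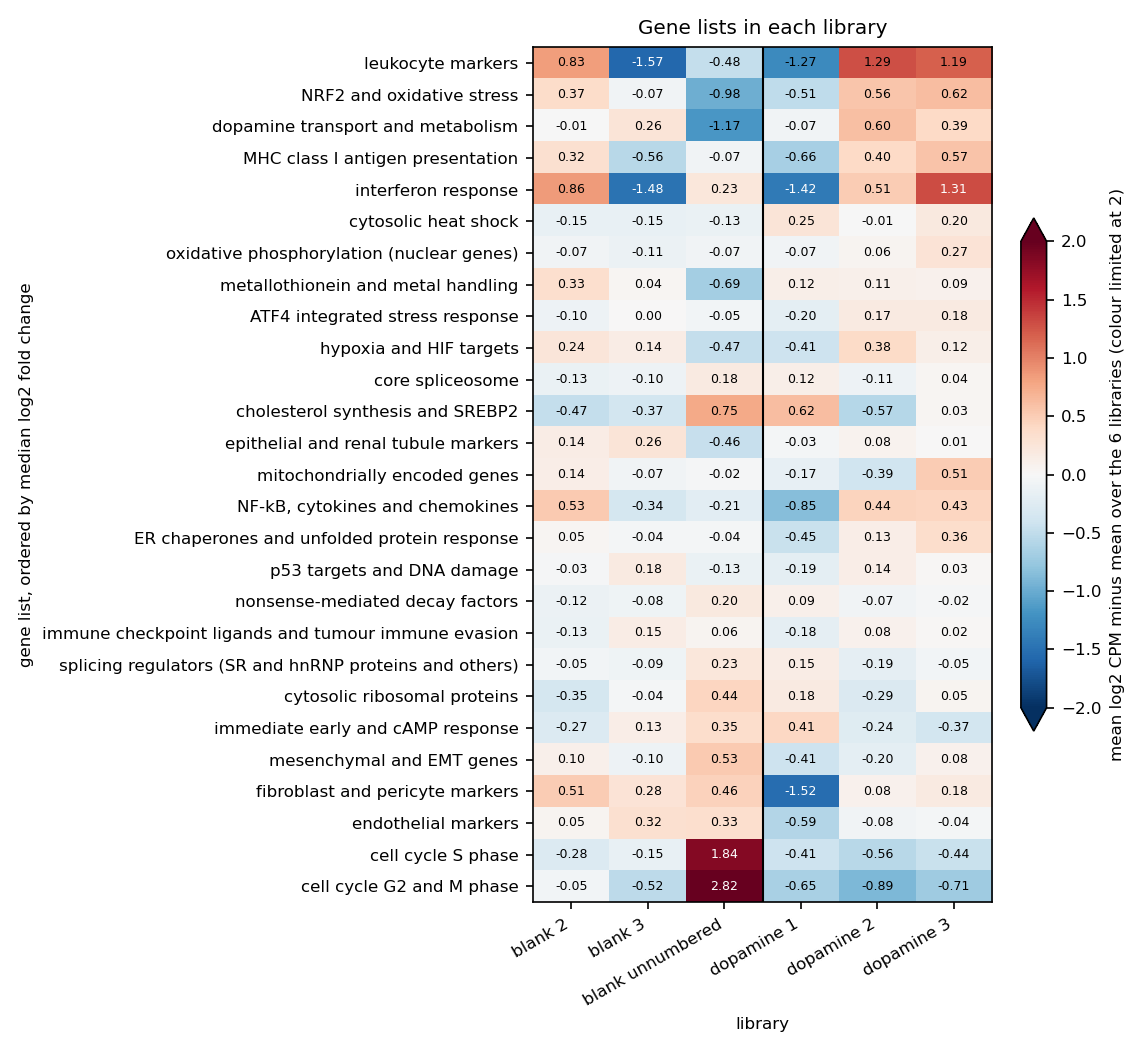
Mean log2 CPM of each of the 27 tested lists in each library, relative to its mean over the 6 libraries (colour and printed value, colour limited at 2), with lists ordered by median log2 fold change and a line between blank and dopamine libraries. The cell cycle lists stand apart in the unnumbered blank library (2.82 for G2 and M phase), fibroblast markers in dopamine 1 (-1.52), and interferon genes are low in blank 3 (-1.48) and dopamine 1 (-1.42).

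The lists of other functions gave no call with all 6 libraries in edgeR with its default filter. Medians were 0.11 for ATF4 targets (33 tested, camera adjusted p = 0.280), 0.06 for cholesterol synthesis (0.383), -0.06 for cytosolic ribosomal proteins (0.533), 0.16 for metallothioneins and metal handling (0.300), -0.03 for p53 targets (0.653), 0.10 for hypoxia targets (0.443) and -0.06 for immediate early genes (0.184). Median, mean and camera direction differed in sign for endoplasmic reticulum chaperones (median -0.02, mean 0.08, up, 0.978), mitochondrially encoded genes (0.0038, 0.04, down, 0.854) and NF-kB targets and cytokines (0.0024, -0.02, down, 0.734). With all 6 libraries, ribosomal proteins passed camera in limma after quantile normalization (-0.14; adjusted p = 0.914 with an estimated correlation) and immediate early genes at an FPKM of at least 5 (-0.09; adjusted p = 0.612 with an estimated correlation). Leaving out a single library moved several others past the threshold. Cholesterol synthesis passed camera without the unnumbered blank library (median 0.57) or dopamine 2 (0.29). Without dopamine 1 its median turned to -0.21 and it did not pass. Ribosomal proteins passed on the higher side without the unnumbered blank library (0.19), and on the lower side without blank 2 (-0.24) or dopamine 1 (-0.16). Immediate early genes passed without blank 2 (-0.16) or dopamine 1 (-0.44), metallothioneins without blank 2 (0.27), and mitochondrially encoded genes without dopamine 3 (-0.34). Without the unnumbered blank library the immediate early median turned to 0.13, not past camera. The median of mitochondrially encoded genes reached 0.18 with a different library left out. ATF4 targets (0.17), endoplasmic reticulum chaperones (0.15) and hypoxia targets (0.16) passed without dopamine 1. With a different library left out, their lowest medians were -0.0080, -0.15 and -0.07. ATF4 targets (0.16), endoplasmic reticulum chaperones (0.20) and immediate early genes (-0.23) also passed with the 4 libraries numbered 2 and 3 alone. With an estimated correlation none of these calls with libraries left out held, at adjusted p of 0.355 to 0.875 by camera. Over the alternatives the camera adjusted p ran from 1.32e-06 to 0.998 for these lists. For these lists edgeR passed 0 members over all genes, with 4 immediate early genes and 1 gene each of the ATF4, metallothionein, p53 and NF-kB lists at an unadjusted p under 0.05. Adjusted over the list alone, Slc1a5 of the ATF4 list passed (edgeR adjusted p = 0.0257). DESeq2 called Slc1a5 and the immediate early gene Zfp36. Vegfa, the angiogenic HIF target, gave 0.01 ± 0.28 and Car9, another HIF target at 2.27 ± 0.47 CPM in blank libraries, -0.28 ± 0.47. The sign for Vegfa turned under 9 alternatives, among them leaving out blank 3 (-0.07) or dopamine 2 (-0.34). Fos, an immediate early transcription factor, was at 34.5 ± 19.5 CPM in blank and 11.9 ± 7.0 CPM in dopamine libraries (-1.53 ± 0.58, edgeR adjusted p = 0.9997).

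Many markers of renal tubule epithelium were low in libraries of both groups, and 8 of 38 (21.1%) reached 10 CPM in all 6. Pax8, a renal lineage transcription factor, stayed at 0.38 to 1.15 CPM, Krt8 at 0.64 CPM or less and Epcam at 0.23 to 5.67 CPM. Slc34a1 and Cdh16 reached at most 0.144 and 0.0959 CPM. The most abundant of the 8 were Lcn2 (47.3 to 5707 CPM), Cp (269 to 3907 CPM) and Spp1 (969 to 3072 CPM). Also among them, the endocytic receptor Lrp2 was at 87.1 to 384 CPM, the water channel Aqp1 at 14.5 to 116 CPM and the tight junction gene Tjp1 at 202 to 452 CPM. Mesenchymal transcripts were abundant, with Vim at 3750 to 8239 CPM and Col1a1 at 266 to 1257 CPM. The leukocyte gene Ptprc and the endothelial gene Pecam1 stayed at 0.64 and 0.77 CPM or less, while the endothelial cadherin Cdh5 was at 5.45 to 206 CPM. The epithelial and renal tubule list (21 tested of 38) had a median log2 fold change of 0.04 and a mean of -0.01 (camera adjusted p = 0.978), and the endothelial list (8 tested of 13) a median of -0.66 (camera adjusted p = 0.184). Without the unnumbered blank library the medians were -0.16 and -0.17. In edgeR, 0 members of these lists passed over all genes or adjusted over the list alone, 2 and 3 had an unadjusted p under 0.05, and DESeq2 called 0.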

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

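Alternatives added after the data were seen were the 4 libraries numbered 2 and 3 without a block, the Tap1 count that the library total leaves, and the tests without mitochondrial and 18S genes. edgeR called 0 genes in each of its alternatives, with 174 to 1372 genes at an unadjusted p under 0.05, and limma called 0 in each of its 6, with 280 to 314. DESeq2 called 20 genes, 6 higher and 14 lower. Camera passed 9 lists with all libraries in edgeR, and 7 (FPKM of at least 5) to 11 (DESeq2) in the other alternatives with all libraries. It passed 8 to 16 with a library left out and 13 with 4 libraries and no block, and 0 with an estimated correlation in each edgeR fit. Fry, run in edgeR with all libraries, also passed 0, and none of the limma calls held with an estimated correlation. The 10 genes of smallest p kept their direction in each alternative that tested them. They had been chosen for no overlap between the groups, which largely fixes that direction. Among genes that turned, Vegfa gave -0.02472 at an FPKM of at least 5. In limma it gave -0.08535 with and without a trend, -0.08909 with the smaller pseudocount, -0.1198 on TPM, -0.05991 with median-of-ratios factors and -0.1102 after quantile normalization. B2m gave -0.05677, -0.05703, -0.08885, -0.03086 and -0.2452 in those limma alternatives, and Drd2 -0.2627 with 4 libraries and no block. With a library left out, values ran from -0.2795 to 1.587 for Drd2, -0.1081 to 0.4853 for Drd4, -0.1844 to 0.3687 for B2m, -0.3668 to 1.016 for Hmox1, -0.3409 to 0.2039 for Vegfa, -0.3955 to 0.08521 for Srsf1 and -0.2413 to 0.1904 for the ribosomal protein list. Of 477 list medians on one side of the threshold with and without the alternative, 65 had the other sign. The cause was not tested.

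With a replicate block, possible only for numbers 2 and 3, edgeR called 0 genes, with 1116 at an unadjusted p under 0.05, and camera passed 14 lists, the interferon list among them (median 1.095) and the mesenchymal list not (-0.2872). The NF-kB list then had a median of 0.1885, on the higher side with camera. With an estimated correlation 0 of the 14 passed, each at a camera adjusted p of 0.751. Deviations of same-numbered libraries correlated at 0.586 for number 2 and -0.272 for number 3, and with 2 such pairs a shared batch is neither shown nor excluded.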

Other observations

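The tests of the cell cycle pattern, of depth, of exchanged labels and of the edgeR splits were chosen after the result was seen, as was the marking of astrocyte genes that kidney also expresses. Genes that varied most between the 6 libraries included Chil1, a chitinase-like protein, at 1.29 to 2417 CPM, the complement component C3 at 17.3 to 8552 CPM and the siderophore-binding protein Lcn2, a member of the renal tubule list, at 47.3 to 5707 CPM. All 3 were highest in dopamine 2 and lowest in the unnumbered blank library. Vgf, a neuropeptide precursor, ran the other way, from 9.72 CPM in dopamine 2 to 1386 CPM in dopamine 1. Xist, also named outside the fixed rule, was at 88.1 to 170 CPM in blank and 33.5 to 71.5 CPM in dopamine libraries (-1.24 ± 0.38, edgeR adjusted p = 0.9997). The Y-linked Ddx3y was at 38.9 to 82.0 CPM in all 6 libraries, which thus each held both transcripts. The cause was not tested.

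Blank 2, dopamine 2 and dopamine 3 stood apart from the other libraries. The 10 splits of 6 libraries are too few for a share under 0.05. DESeq2 called as many genes as between dopamine and blank in 3 of them, that grouping included. edgeR called 0 genes between dopamine and blank and 176 in the highest other split, and DESeq2 20 and 1628. That other split sets these 3 libraries against the rest and points to a structure of the samples that the labels do not give. A difference in total counts as the whole cause is argued against, since that split still gave 159 to 181 genes in 10 random thinnings of the libraries to equal totals, and blank 2 held 17954949 counts, fewer than blank 3 (18179787) and the unnumbered blank library (19766071) and more than dopamine 1 (16771499). Exchanged labels of blank 2 and dopamine 1 may account for it and stay open. Dopamine 1 correlated with the other blank libraries at 0.9197 or more, against 0.908 between those. That comparison cannot decide, because blank 2 also exceeded 0.908 with both, at 0.950 with blank 3 and 0.912 with the unnumbered blank library. A difference between cultures or preparations stays open as untested.

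Cell cycle genes lay on the lower side with dopamine, and both list calls were lost with an estimated correlation (camera adjusted p = 0.591 for each). Without the unnumbered blank library the G2 and M phase median was -0.3278 against -2.38 with it, so that library alone may account for most of the difference. A lower rate of division in all dopamine libraries cannot be told apart for the rest. Each dopamine library had a lower list mean than each blank library, but the adjusted p with an estimated correlation was 0.6765 without the unnumbered blank library.

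Gfap, an intermediate filament gene typical of astrocytes, was at 1219 to 1630 CPM in blank 2, dopamine 2 and dopamine 3, 815 in blank 3, 102 in dopamine 1 and 32.4 in the unnumbered blank library, all labelled as renal carcinoma cells. Lcn2 (3363 to 5707 CPM) and C3 (4660 to 8552 CPM) were also highest in blank 2, dopamine 2 and dopamine 3. Both were lowest in the unnumbered blank library. The place of Lcn2 on the renal tubule list thus does not show which cells its transcripts came from. Of 25 astrocyte markers 72% reached 10 CPM in all 6 libraries, among them Slc1a3 (1305 to 2393 CPM in the first 3 of these libraries and 91.0 to 490 in the others), Apoe (194 to 3844 over all 6) and Aqp4 (70.4 to 679), against 21.1% of renal tubule, 35.7% of neuron, 33.3% of oligodendrocyte, 25% of Schwann cell, 27.3% of renal stroma and podocyte, 47.4% of fibroblast, 23.1% of endothelial and 3.85% of leukocyte markers. Kidney or renal carcinoma also expresses 13 of the 25, and of the other 12 50% reached that level. Of the 25, S100b stayed at 2.43 CPM or less, Agt at 1.46, Ntsr2 at 1.15 and Gjb6 at 0.41. Cells with astrocyte genes may make up most of the libraries by this count. However, a count of markers cannot tell this from a smaller share of cells with high levels, and the share per library was not measured. Olig2 (111 and 142 CPM, 21.8 to 24.2 elsewhere) and the neuron gene Gad2 (23.9 and 29.9, 0.57 to 2.03 elsewhere) were instead highest in the unnumbered blank library and dopamine 1. Neuron markers did not all follow Gad2. Gad1 was also highest there (44.0 and 83.3 CPM), but Map2 and Tubb3 were highest in blank 3 (324 and 46.5 CPM). Both were lowest in the unnumbered blank library (71.2 and 9.11 CPM). A smaller share of astrocyte RNA among renal cells, and expression of these genes by the labelled cells themselves, stay open as untested.

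Tap1, a peptide transporter gene of class I presentation, had 3322 counts in dopamine 1, where its deposited FPKM of 15.5 corresponds to 1424 counts. The FPKM values of the other 56690 genes imply a library total 2995 to 3000 counts lower, which leaves Tap1 322 to 327 counts. With 322 counts its log2 fold change was 0.12 in place of 1.14. The count of 1424 was not tested, and which count is right stays open.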
